A study of Mus musculus with 9 samples.

How the data were processed

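Total RNA of 9 samples of mouse stomach cells was labelled with biotin by the standard Affymetrix procedure and hybridised to 1 Affymetrix mouse genome array per sample, per the labels' protocols. The 9 samples form 3 groups of 3. The chief group is Mist1+ Tomato+ cells of the gastric corpus, the isthmus group is Mist1+ Tomato+ cells of the corpus after ablation of Lgr5+ cells, and the parietal group is gastric parietal cells. The Mist1+ Tomato+ cells were sorted by flow cytometry, per the labels. How the parietal cells were collected is not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

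The deposited values are log2 signals, 1 per probe set and array, made by the authors with the Affymetrix MAS5 algorithm, per the submitters' processing notes. The MAS5 version, the step to the log scale and the floor at 0 are not given in the sources used here, and the log base was settled from the values. With base 2 the mean signal, trimmed by 2% at each end, was 496 to 497 on each of the 9 arrays, as MAS5 scaling to one target gives. The table used here holds 45037 probe sets. Between 1.99% and 3.91% of an array's values were exactly 0, which was read as a floor, and 153 of these values belonged to tested genes. No detection calls, control probe sets or scanner files were used here, so RNA quality from 3' to 5' ratios and spiked controls was not analysed here.

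Probe sets were named from the platform annotation, and symbols were looked up through the Entrez identifier in a RefSeq table of the mouse assembly GRCm38.p6. Of the probe sets, 34945 named 1 gene, 932 named several and 9160 named none. The table matched 34741 of them and changed 0 symbols. A gene was represented by its probe set with the highest mean over the 9 arrays. Folds and bounds are those of that probe set, and a gene's other probe sets can differ. Of 18193 genes with a probe set, the 11053 with a signal above the array median on at least 3 of the 9 arrays were tested. No genome was used, so no coordinates are given.

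Differences between groups were tested in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend) on the deposited log2 values as they are. One fit held a mean for each of the 3 groups and all 9 arrays, with 6 residual degrees of freedom, so that the groups shared one estimate of the spread. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 11053 genes within each comparison, and a call was an adjusted p under 0.05 with no minimum fold. All adjusted p-values given for single genes come from limma. The choice of test had been written for linear signals with a pseudocount of 16, with the provision that values already on the log2 scale would be used unaltered. Where an array of the dimmer group lay below its own array median, the fold is given as a lower bound, "at least". For it each dim array was set to the higher of its own value and its array median, a stand-in for background that was chosen after the values had been seen. List medians called floored treat the arrays of both groups so, and are given where they differ. The number of arrays limits the precision, and the labels do not say whether the samples came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

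Gene lists were tested with limma's camera on the same fit with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists tested in a comparison. Of 34 lists, 27 had at least 5 tested members. Camera with an estimated correlation was run beside it, as was fry, which tests whether a list's genes move on balance one way and compares the list with no other genes. Each list's calls were counted after adjustment over all genes and again "adjusted over the list alone". The lists, the groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined.

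The genes the text names were taken from those the following rule gives. For each comparison it takes the 8 genes with the largest log2 difference in each direction among called genes whose groups do not overlap and whose mean signal is above the mean array median, leaving out unnamed clones. For each list it takes up to 4 called members with the largest difference or, where none was called, the 2 brightest. For each set of genes highest in one group it takes the 6 with the largest smaller difference among genes that pass the same limits on mean signal, overlap and unnamed clones. It always includes Lgr5, Bhlha15, Gper1, Cblif, Pgc, Atp4a, Atp4b, Muc6, Tff2, Gkn3, Muc5ac, Gkn2, Mki67, Stmn1, Sox9, Cd44 and Pdk1 to Pdk4. Muc6 was not analysed here because no probe set used here names it alone. The text names a part of these genes for length, and the counts over alternatives cover all of them. Genes given per array for sex, blood, connective tissue and antral cells were chosen after their values had been seen.

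Alternatives were pseudocounts of 1 and 64 added to the signal before log2, no filter, a filter at the 75th percentile of each array, quantile normalization, centring of each array on its median, eBayes without a trend, estimated array weights, a fit of only the 6 arrays compared, the mean of a gene's probe sets, leaving out probe sets whose names end in _x_at or _s_at, a fold of at least 2, the replicate number as a block, and leaving out each array in turn. A pseudocount of 16 and leaving out both arrays with high Xist were added after the data had been seen. The fits and list tests were tested on simulated data with the spread of the real genes. With 200 of 11053 genes changed by a log2 value of 1, 2 or 4, the isthmus and chief comparison recovered 7.70%, 39.1% and 79.8% of them over 10 simulations. The parietal and chief comparison recovered 7.25%, 41.8% and 79.2%, and the isthmus and parietal comparison recovered 7.00%, 41.8% and 79.2%. Between 0.709% and 6.45% of these calls were false. A simulated list of 20 genes shifted by 1 was called in 10 of 10 simulations of each comparison, with 0 calls by camera among the lists that were not shifted. These simulations drew each gene independently, so they do not show how often camera calls lists of correlated genes. Other splits of the real arrays gave up to 8 list calls for isthmus and chief, 16 for parietal and chief, and 17 for isthmus and parietal. Each of these splits mixes arrays of both groups and keeps a part of any real difference, so these counts are not a rate of false calls.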

Results

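Gene expression was profiled in 9 samples of mouse stomach cells, each on its own Affymetrix array, in 3 groups of 3. The chief group held cells of the gastric corpus labelled Mist1+ Tomato+, Tomato being a red fluorescent reporter. Mist1, the product of Bhlha15, is a transcription factor of enzyme-secreting cells. Whether the sort read Mist1 itself or only the reporter was not analysed here. The isthmus group held Mist1+ Tomato+ corpus cells collected after cells expressing Lgr5, a receptor of the Wnt pathway used as a stem cell marker, had been ablated. The parietal group held gastric parietal cells, which secrete acid. The median signal per array lay between 55.7 and 104, and the 100 brightest probe sets held 4.72% to 7.49% of an array's signal. Over the 11053 genes tested, log2 values correlated at r = 0.803 to 0.828 within the chief group, 0.847 to 0.852 within the isthmus group and 0.884 to 0.894 within the parietal group. Chief and isthmus arrays correlated at 0.753 to 0.825, while parietal arrays correlated with either at 0.664 to 0.716. The first principal component held 45.0% of the variance and parted the parietal arrays from both Mist1+ groups, and the second held 13.8% and parted chief from isthmus arrays. No 2 arrays had the same profile, the smallest median absolute difference between any pair being 0.74 log2 and the highest share of probe sets with equal values 1.29%.

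Lgr5, the gene by which cells had been ablated, had log2 signals of 8.05, 7.54 and 9.36 in the chief samples, 2.93, 4.83 and 5.97 in the isthmus samples, and 4.62, 6.26 and 4.0 in the parietal samples. Each isthmus array lay below each chief array. The isthmus mean lay below the mean of its array medians, which bounds the difference at 4.48-fold or more, and it did not pass the limma test (adjusted p = 0.0916). It passed with a pseudocount of 64 (adjusted p = 0.0337, and 0.0337 to 0.251 over all alternatives). Bhlha15 was 10.75, 10.05 and 9.20 log2 in the chief and 5.03, 1.34 and 7.36 in the isthmus samples, also labelled Mist1+ Tomato+. The difference, bounded in the same way at 11.3-fold or more, missed the threshold (adjusted p = 0.123) except with a pseudocount of 16 or 64, with a range of 0.00928 to 0.294 over all alternatives.

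**Figure D1:**
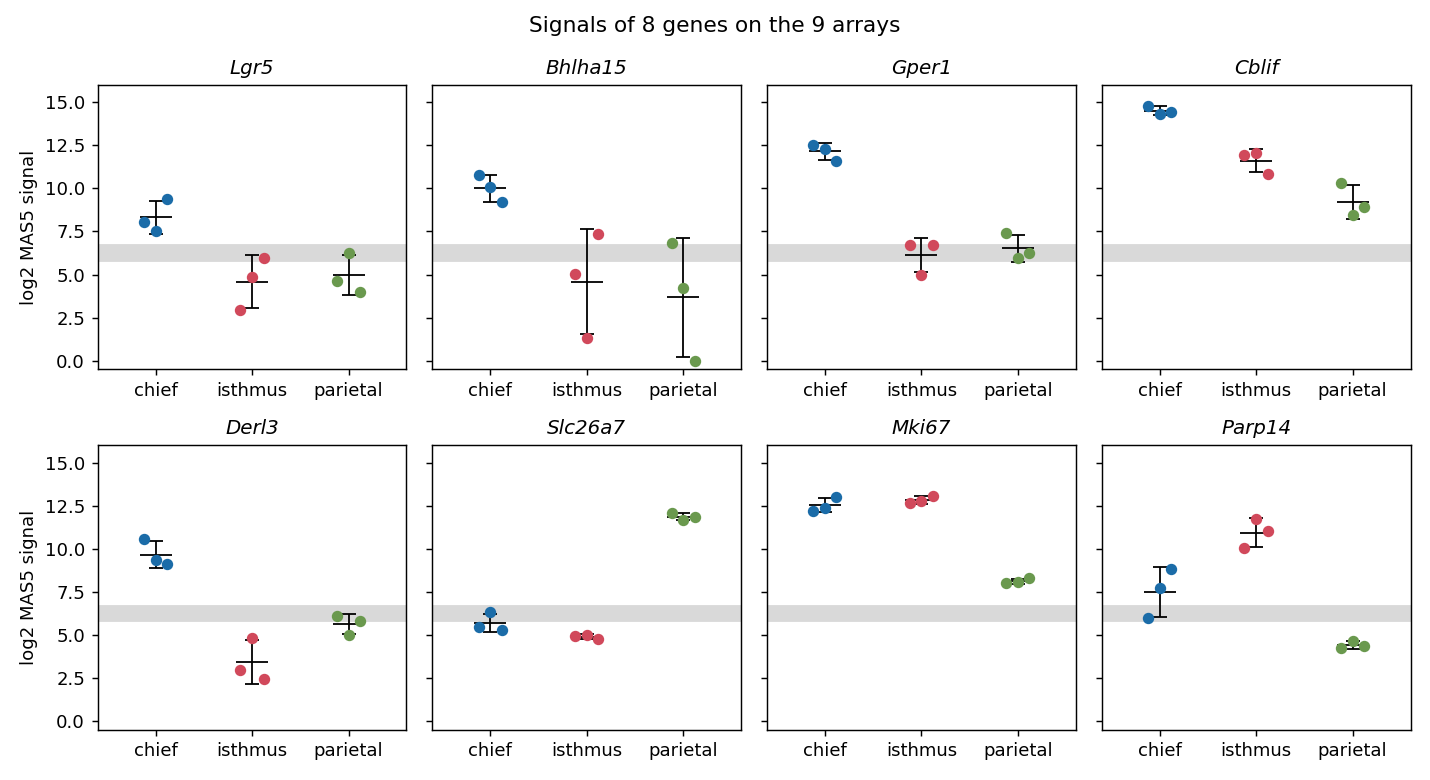
Log2 MAS5 signals of 8 genes (vertical axis) in the chief, isthmus and parietal groups (horizontal axis), with a point for each of the 3 arrays per group, a horizontal line at the group mean, bars of 1 SD, and a grey band over the range of the array medians, 5.80 to 6.70. Gper1 was 12.14 in the chief group and 6.12 in the isthmus group, inside the grey band, whereas Mki67 stayed at 12.52 and 12.84 in these groups and was 8.13 in the parietal group.

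The isthmus samples were compared with the chief samples to ask how Mist1+ cells differ once Lgr5+ cells are gone. Several genes of enzyme-secreting cells were far lower in the isthmus samples. Gper1, a membrane receptor for estrogen, fell at least 48.6-fold from 12.14 ± 0.48 log2 to 6.12 ± 1.0 (SD, n = 3 each; adjusted p = 0.000525), and its other probe set went the same way, from 10.59 to 5.30. Sostdc1, a secreted antagonist of BMP and Wnt signals, fell at least 54.6-fold (adjusted p = 0.000779), and Derl3, a component of endoplasmic reticulum (ER) associated degradation, fell at least 11.4-fold (adjusted p = 0.00612). Cblif, the gastric intrinsic factor, was 7.40-fold lower, at 11.61 ± 0.66 against 14.50 ± 0.26 (SD, n = 3 each; adjusted p = 0.00707). Parp14, an ADP-ribosyltransferase, rose at least 9.83-fold (adjusted p = 0.0428), a call kept only without chief replicate 3 when single arrays were left out (adjusted p of up to 0.144). Usp18, an interferon-induced protease that removes Isg15 from proteins, rose at least 5.46-fold (adjusted p = 0.0396), a call that ended whichever of the 9 arrays was left out (adjusted p = 0.0558 to 0.142).

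Among the other genes with large differences, Fes, a tyrosine kinase, fell at least 13.7-fold, Copz2, a subunit of the COPI vesicle coat, fell at least 17.2-fold, and Htra1, a secreted serine protease, fell at least 7.87-fold. Smoc2, a matricellular protein, fell at least 3.74-fold. Slc25a25, a mitochondrial carrier, rose 6.28-fold, Nr1h4, the bile acid receptor, at least 5.54-fold, and Trim21, a ubiquitin ligase and Fc receptor, 5.40-fold. Rbm34 rose 5.29-fold by the probe set used, while its other probe set was lower in the isthmus samples, at 6.35 against 7.17 log2. Without chief replicate 1, 30 of the 34 named genes called in this comparison lost their calls, with adjusted p-values of up to 0.16, and Gper1, Sostdc1, Copz2 and Ndufa1 kept theirs. All 34 kept their sign. The calls of Nr1h4, Smoc2 and Acadl ended whichever array was left out (adjusted p = 0.0558 to 0.119, 0.0549 to 0.159 and 0.0567 to 0.14). That of Htra1 was kept only without isthmus replicate 2 (highest 0.147), and those of Trim21 and Rbm34 were kept without 3 of the 9 arrays (highest 0.14 and 0.15). Without isthmus replicate 1 it was 25 of 34, with adjusted p-values of up to 0.167, and without any 1 of the other arrays between 14 and 20. Gper1, Sostdc1 and Copz2 were called under every alternative that was run.

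Of the 10 chief cell markers tested, 5 fell, 0 rose and 5 did not pass, and 8 fell when adjusted over the list alone. The list had a median log2 difference of -1.57, or -1.56 when floored, that is with each array at the higher of its own value and its array median (camera adjusted p = 1.1e-10; adjusted p = 0.0688 with an estimated correlation). The lists were written from general knowledge of the stomach, and Gper1 may have become known as a chief cell gene through these very samples, so its part in this count is not independent evidence. Besides Gper1 and Cblif, Clps, pancreatic colipase, fell 2.11-fold, Xbp1, a regulator of secretory capacity, 2.11-fold, and Pgc, the zymogen pepsinogen C, 1.87-fold (adjusted p = 0.0161, 0.0324 and 0.00877). After quantile normalization the calls of Pgc and Clps ended (adjusted p = 0.26 and 0.221, each the highest over its alternatives), and that of the list did not. Of 29 genes of ER protein folding and the unfolded protein response, 5 fell and 0 rose, with 18 falling when adjusted over the list alone, and the median was -0.74 (camera adjusted p = 6.95e-14; adjusted p = 0.151 with an estimated correlation). Its called members included Derl3, the chaperone Hyou1 (-1.37), the translocon protein Ssr4 (-1.15) and the co-chaperone Dnajb9 (-1.12). When single arrays were left out, the calls of Ssr4 and Dnajb9 were kept only without chief replicate 3 (highest adjusted p 0.127 and 0.158), and that of Hyou1 only without chief replicate 2 or parietal replicate 2 (highest 0.16). Of 5 pancreatic acinar genes, 0 passed, 1 fell when adjusted over the list alone, and the median was -2.84, or -1.55 floored (camera adjusted p = 0.0262; adjusted p = 0.202 with an estimated correlation). That call ended without chief replicate 3 (adjusted p = 0.08), without isthmus replicate 1 (0.128, median -1.11) and with no filter (0.135), within a range of 0.000616 to 0.202. Its brightest member, the lipase Pnliprp2, was 13.88 log2 in the chief and 9.65 in the isthmus samples (adjusted p = 0.0575).

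Cell cycle genes lay higher in the isthmus samples as a list, with no single member called. Of 39 tested, 0 passed by limma, also when adjusted over the list alone, and 7, all higher, had an unadjusted p under 0.05. The median difference was 1.04 (camera adjusted p = 4.78e-07; adjusted p = 0.297 with an estimated correlation, and fry gave 0.102). Without chief replicate 1 the median was 0.60 (adjusted p = 0.00134). Mki67, the Ki-67 proliferation antigen, was 12.52 ± 0.40 log2 in the chief and 12.84 ± 0.21 in the isthmus samples (SD, n = 3 each; limma adjusted p = 0.563). Of 21 interferon response genes 1 rose, Usp18, whose call ended without any 1 array (adjusted p = 0.0558 to 0.142), and 2 when adjusted over the list alone, with a median of 1.44, or 1.32 floored (camera adjusted p = 9.43e-07; adjusted p = 0.151 with an estimated correlation). Of 20 ribosome biogenesis genes 0 passed over all genes and 5 rose when adjusted over the list alone (median 0.48, camera adjusted p = 0.000345; adjusted p = 0.227 with an estimated correlation). Of 19 genes of fatty acid oxidation, Acadl, a long-chain acyl-CoA dehydrogenase, rose 1.89-fold, also when adjusted over the list alone, but its call over all genes ended without any 1 array (adjusted p = 0.0567 to 0.14). The median was 0.29 (camera adjusted p = 0.0296; adjusted p = 0.227 with an estimated correlation). Without chief replicate 1 the median was 0.08 (adjusted p = 0.0484). The call ended without chief replicate 3 (adjusted p = 0.0624), without isthmus replicate 3 (0.153) and after centring each array (0.0681), within a range of 0.0045 to 0.227.

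Lists of other gastric cells were lower or gave no call. Of 10 surface pit cell markers, 5 fell, the same number when adjusted over the list alone, and 0 rose, with a median of -0.51 (camera adjusted p = 4.83e-05; adjusted p = 0.151 with an estimated correlation). The mucosal proteins Psca, Gkn1, Gkn2 and Tff1 had differences of -0.72, -0.66, -0.63 and -0.58. Of 45 genes of oxidative phosphorylation, 2 fell, Ndufa1 (-1.31) and Uqcrb (-0.49), and 16 when adjusted over the list alone, with a median of -0.19 (camera adjusted p = 3.41e-07; adjusted p = 0.414 with an estimated correlation, and fry gave 0.125). Without isthmus replicate 3 the median of oxidative phosphorylation was -0.29 (adjusted p = 3.13e-10). Both calls ended after quantile normalization, which moved the median of the pit list to -0.08 (adjusted p = 0.171) and turned that of oxidative phosphorylation to 0.03 (adjusted p = 0.939). Of 14 enteroendocrine markers 1 fell, Sst, the hormone somatostatin (-1.49, kept only without parietal replicate 2 or 3 when single arrays were left out, highest adjusted p 0.147), also when adjusted over the list alone, and the median was -1.13, or -1.02 floored (camera adjusted p = 0.00158; adjusted p = 0.151 with an estimated correlation). The other 17 lists gave no call. The parietal, neck and tuft lists had camera adjusted p-values of 0.64, 0.388 and 0.674, and Atp4a and Atp4b differed by -0.49 and -0.22 (limma adjusted p = 0.393 and 0.564). For stem and progenitor markers the median was 0.16, or -0.11 floored, while the mean was -0.38 and the test pointed down (adjusted p = 0.584), and for Wnt targets the median was 0.12, or -0.23 floored, and the mean -0.27, again with a test pointing down (adjusted p = 0.824). The other camera adjusted p-values were 0.584 for the metaplasia, EGF receptor and immediate early lists, 0.377 for regulated secretion, 0.3 for glycolysis, 0.306 for the tricarboxylic acid cycle, pyruvate dehydrogenase kinase and Notch lists, 0.723 for p53 targets and 0.768 for cholesterol synthesis. The pyruvate dehydrogenase kinases Pdk1, Pdk2, Pdk3 and Pdk4 differed by 1.01, -1.08, 0.00 and 1.42, with none called by limma (adjusted p = 0.234, 0.237, 0.999 and 0.1). These kinases, too, may have been listed through knowledge of these samples.

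Signals of other cells moved between these arrays. Chief replicate 3 stood apart in several connective tissue genes, with Col1a1 at 12.48 log2 against 1.30 to 7.26 on the other arrays of both groups, and Sparc at 12.76. The haemoglobin gene Hbb-b2 was at 9.84, 9.56 and 14.11 in the chief samples and at most 5.75 in the isthmus samples (adjusted p = 0.0455). Of other haemoglobin genes, Hba-a2 was at 11.29 to 12.25 on all 9 arrays, and Hba-a1, which was not among the genes tested, at 0.11 to 2.78. These probe sets thus differ on how much haemoglobin RNA the arrays held. Chief replicate 3 also had Xist at 11.72, together with the Y-linked Eif2s3y at 10.63. Gast, the antral hormone gastrin, was 14.48, 3.65 and 13.84 in the chief and 11.38, 3.66 and 14.07 in the isthmus samples. The leukocyte and fibroblast lists, 5 tested members each, had floored medians of -0.71 and -1.21 between isthmus and chief (camera adjusted p = 0.0813 for each). The leukocyte list was called without chief replicate 2 (adjusted p = 0.022, range 0.022 to 0.254) and the fibroblast list without chief replicate 1 (0.000735, range 0.000735 to 0.531).

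In all, 42 genes were higher and 137 lower in the isthmus samples by limma, 118 of these 179 differed by at least 2-fold, and 1924 genes had an unadjusted p under 0.05. The arrays of both groups did not overlap for 2338 genes, 21.1% of those tested, where chance gives 10%. Camera called 10 of 27 lists, 4 up and 6 down, 0 of them with an estimated correlation (lowest adjusted p = 0.0688), and fry called 6. The counts of genes often fell when 1 array was left out. This held for parietal arrays too, which enter this comparison only through the shared estimate of the spread. With only the chief and isthmus arrays in the fit, 19 genes were higher and 72 lower, so the counts rest in part on that shared estimate. Without chief replicate 1 there were 0 higher and 19 lower, without isthmus replicate 1 there were 2 and 34, and without isthmus replicate 2 there were 9 and 74. The higher genes were 24 without isthmus replicate 3 and 19, 18 and 15 without parietal replicate 1, 2 or 3. The lower genes were 85 without chief replicate 3 and 88 and 82 without parietal replicate 2 or 3. Without both arrays with high Xist, chief replicate 3 and parietal replicate 1, the counts were 19 and 55.

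The parietal samples were compared with the chief samples, which are sorted Mist1+ Tomato+ cells. The chief arrays also held bright transcripts of other lineages and of dividing cells. Ghrl, the hormone ghrelin, was at 13.81 to 14.11 log2 there, the pit cell mucin Muc5ac at 13.52 to 13.82 and Mki67 at 12.22 to 12.98. Differences in such genes therefore need not be differences between parietal and chief cells. Slc26a7, an anion exchanger of the parietal cell, rose at least 40.3-fold to 11.86 ± 0.19 log2 from 5.70 ± 0.54 (SD, n = 3 each; adjusted p = 1.39e-05). The proton pump subunit Atp4b rose 3.07-fold, to 14.25 ± 0.14 from 12.63 ± 0.11 (SD, n = 3 each; adjusted p = 4.68e-05), and the subunit Atp4a 2.07-fold (adjusted p = 0.0154), a call lost without chief replicate 3 (adjusted p = 0.0637), without parietal replicate 3 (0.0547) and without both arrays with high Xist (0.126, the highest over all alternatives). Cblif was 38.9-fold lower in the parietal samples (adjusted p = 5.23e-06), Gper1 49.5-fold lower (adjusted p = 4.92e-05) and Mki67 21.1-fold lower (adjusted p = 3.39e-07). The proton pump genes were bright on the sorted Mist1+ arrays too, at 11.97 to 12.80 log2 for Atp4b.

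Large rises included B4galnt2, a glycosyltransferase, at least 86.0-fold, Fabp1, a fatty acid binding protein, at least 44.2-fold, the ribonuclease Rnase1 at least 28.9-fold, the glucose transporter Slc2a4 at least 27.6-fold, and Gpr155 at least 67.2-fold. Pfkfb3, an enzyme that sets the level of a glycolytic activator, rose at least 16.9-fold. Large falls included the imprinted gene Peg3, at least 40.5-fold, the lipases Pnliprp2 and Pnliprp1, at least 188-fold and 44.8-fold, and Sostdc1, at least 68.0-fold. Bhlha15 fell at least 14.3-fold (adjusted p = 0.0157; 0.0562 without chief replicate 1 and 0.0552 without parietal replicate 3, range 0.000511 to 0.0566). Lgr5 fell at least 5.02-fold (adjusted p = 0.0322), a call lost without chief replicate 1, chief replicate 3, parietal replicate 1 or parietal replicate 3 (adjusted p = 0.0644, 0.125, 0.0821 and 0.107) and after quantile normalization (0.0533), within a range of 0.00716 to 0.226.

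Of 21 parietal cell markers, 18 rose, 0 fell and 3 did not pass, and 18 rose and 2 fell when adjusted over the list alone (median 1.71, camera adjusted p = 1.81e-11; adjusted p = 0.0693 with an estimated correlation). They included the water channel Aqp4, at least 19.6-fold, and the histamine receptor Hrh2, at least 13.6-fold. Energy metabolism rose with them. Of 45 genes of oxidative phosphorylation 38 rose, 40 when adjusted over the list alone (median 0.72, camera adjusted p = 2.58e-22; adjusted p = 0.0693 with an estimated correlation), among them Uqcrfs1 by 3.72-fold and Ndufs1 by 1.82 log2. Of 19 genes of the tricarboxylic acid cycle and pyruvate entry 18 rose, 19 when adjusted over the list alone (median 1.13, camera adjusted p = 6.18e-14), and of 19 genes of fatty acid oxidation 13 rose, 16 when adjusted over the list alone (median 0.98, camera adjusted p = 1.28e-10). Both calls held with an estimated correlation. The coactivator Ppargc1a rose by 2.65 and the hydratase Echs1 by 2.25 log2. Of 15 glycolysis genes 9 rose, the same number when adjusted over the list alone (median 0.66, camera adjusted p = 2.45e-05; adjusted p = 0.0693 with an estimated correlation), with Ldhb and Pfkl up by 2.03 and 2.11. Of 7 pyruvate dehydrogenase kinases and phosphatases 3 rose, also when adjusted over the list alone (median 1.40, 1.18 floored, camera adjusted p = 0.0127; adjusted p = 0.0839 with an estimated correlation). Pdk4 rose by 1.78 (limma adjusted p = 0.00651) and Pdk1 by 1.40 (adjusted p = 0.0265; 0.0888 without chief replicate 1 and 0.115 without parietal replicate 2, range 0.0141 to 0.115).

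Lists of the other gastric lineages were lower in the parietal samples. Of 10 chief cell markers 9 fell, the same number when adjusted over the list alone (median -3.24, -2.79 floored, camera adjusted p = 2.8e-07), a count that again includes Gper1, and of 10 mucous neck cell markers 10 fell (median -2.71, -2.38 floored, camera adjusted p = 6.98e-07; adjusted p = 0.05 with an estimated correlation), with the transcription factor Spdef at least 17.5-fold lower and the trefoil peptide Tff2 lower by -1.91. Of 10 pit cell markers 8 fell, also when adjusted over the list alone (median -1.13, camera adjusted p = 7.36e-08), with the mucins Muc1 and Muc5ac 18.2-fold and 11.5-fold lower. Of 14 enteroendocrine markers 12 fell, 14 when adjusted over the list alone (median -6.38, -4.28 floored, camera adjusted p = 1.24e-10). Chga, the granule protein chromogranin A, fell at least 119-fold, and Hdc, which makes histamine, at least 49.2-fold. The chief, pit and enteroendocrine calls held with an estimated correlation. Of 6 tuft cell markers 2 fell, 3 when adjusted over the list alone (median -3.57, -1.44 floored, camera adjusted p = 0.0324; adjusted p = 0.195 with an estimated correlation), a call that ended without chief replicate 3 (adjusted p = 0.129, range 0.00229 to 0.195). Of 5 pancreatic acinar genes 3 fell, 5 when adjusted over the list alone (floored median -2.51, camera adjusted p = 0.000865; adjusted p = 0.05 with an estimated correlation).

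Of 39 cell cycle genes, 30 fell and 1 rose, 32 and 1 when adjusted over the list alone (median -3.07, -2.20 floored, camera adjusted p = 1.16e-12; adjusted p = 0.0839 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell at least 14.2-fold, and the spindle factor Tpx2 at least 9.02-fold. Of 18 stem and progenitor markers 10 fell and 3 rose, the same when adjusted over the list alone (median -1.85, -1.44 floored, camera adjusted p = 0.0328; adjusted p = 0.147 with an estimated correlation). Olfm4 rose at least 7.36-fold and the Wnt target Axin2 fell at least 7.50-fold. This call ended without chief replicate 2 or 3 (adjusted p = 0.0525 and 0.0777) and with the stricter filter (0.482, the highest over all alternatives). Of 13 Wnt targets 5 fell, 8 when adjusted over the list alone (median -2.47, -1.55 floored, camera adjusted p = 0.00364; adjusted p = 0.0526 with an estimated correlation and 0.151 with the stricter filter). The Wnt median was -1.49 without chief replicate 3 and -1.37 without parietal replicate 3 (adjusted p = 0.00793 and 0.00839). Of 15 genes of spasmolytic polypeptide-expressing metaplasia 11 fell and 2 rose, also when adjusted over the list alone (median -2.44, -2.18 floored, camera adjusted p = 0.00114; adjusted p = 0.272 with an estimated correlation). Of 29 ER folding genes 16 fell, 17 when adjusted over the list alone (median -0.57, camera adjusted p = 1.73e-06; adjusted p = 0.174 with an estimated correlation), among them Derl3 at least 13.4-fold and Sdf2l1 by -3.03. Of 21 interferon response genes 5 fell, also when adjusted over the list alone (median -1.81, -1.20 floored, camera adjusted p = 0.000704; adjusted p = 0.0902 with an estimated correlation). Of 22 immediate early and dissociation stress genes 10 fell, 15 when adjusted over the list alone (median -1.18, -1.16 floored, camera adjusted p = 9.46e-06, held with an estimated correlation), with Klf4 and Fosb lower by -4.20 and -4.95. The remaining 8 lists gave no call, with camera adjusted p-values of 0.0624 for the Notch and ribosome biogenesis lists, 0.572 for EGF receptor genes, 0.543 for p53 targets, 0.877 for regulated secretion and for cholesterol synthesis, 0.552 for leukocyte and 0.344 for fibroblast markers. The fibroblast list was called without chief replicate 1 (adjusted p = 0.0406, range 0.0406 to 0.975), the Notch list without parietal replicate 2 (0.0219, range 0.00229 to 0.195), and the ribosome biogenesis list without chief replicate 1 or parietal replicate 1 (0.0327 and 0.0268, range 0.0202 to 0.371). For regulated secretion the median was 0.02, the mean -0.60 and the test pointed up, and for leukocyte markers the median was 0.19, or -0.40 floored, the mean -0.93 and the test pointed down.

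Markers of other cells differed as well. Kit, a receptor of mast and pacemaker cells, was 10.80, 11.25 and 11.42 log2 on the parietal arrays and rose at least 24.7-fold, and Plvap, an endothelial protein, was 9.34 to 10.46 there and rose at least 10.9-fold. Neither moved with its list. Of 3 mast cell markers tested Kit rose and the other 2 fell (floored median -2.38), and of 3 endothelial markers Plvap alone was called (median 0.35). Cd74, a leukocyte protein of antigen presentation, fell at least 10.4-fold. The hormone Gast was 1.62, 6.76 and 1.48 on the parietal arrays. Parietal replicate 1 had Xist at 13.13 and Eif2s3y at 2.84, whereas the other parietal arrays had Xist at 5.93 and 5.65.

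By limma 1175 genes were higher and 1500 lower in the parietal samples, 2140 of them by at least 2-fold. The groups did not overlap for 4397 genes, 39.8% of those tested, where chance gives 10%. The median log2 difference of all genes was -0.11, and centring each array on its median moved it to 0.05 and the counts to 1553 higher and 1272 lower, so that 55.0% of calls were higher rather than 43.9%. Camera called 19 of 27 lists, 6 up and 13 down, 6 of them also with an estimated correlation, and fry called 22. Without parietal replicate 3 the higher genes numbered 757, and without both arrays with high Xist the counts were 645 higher and 961 lower.

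**Figure D2:**
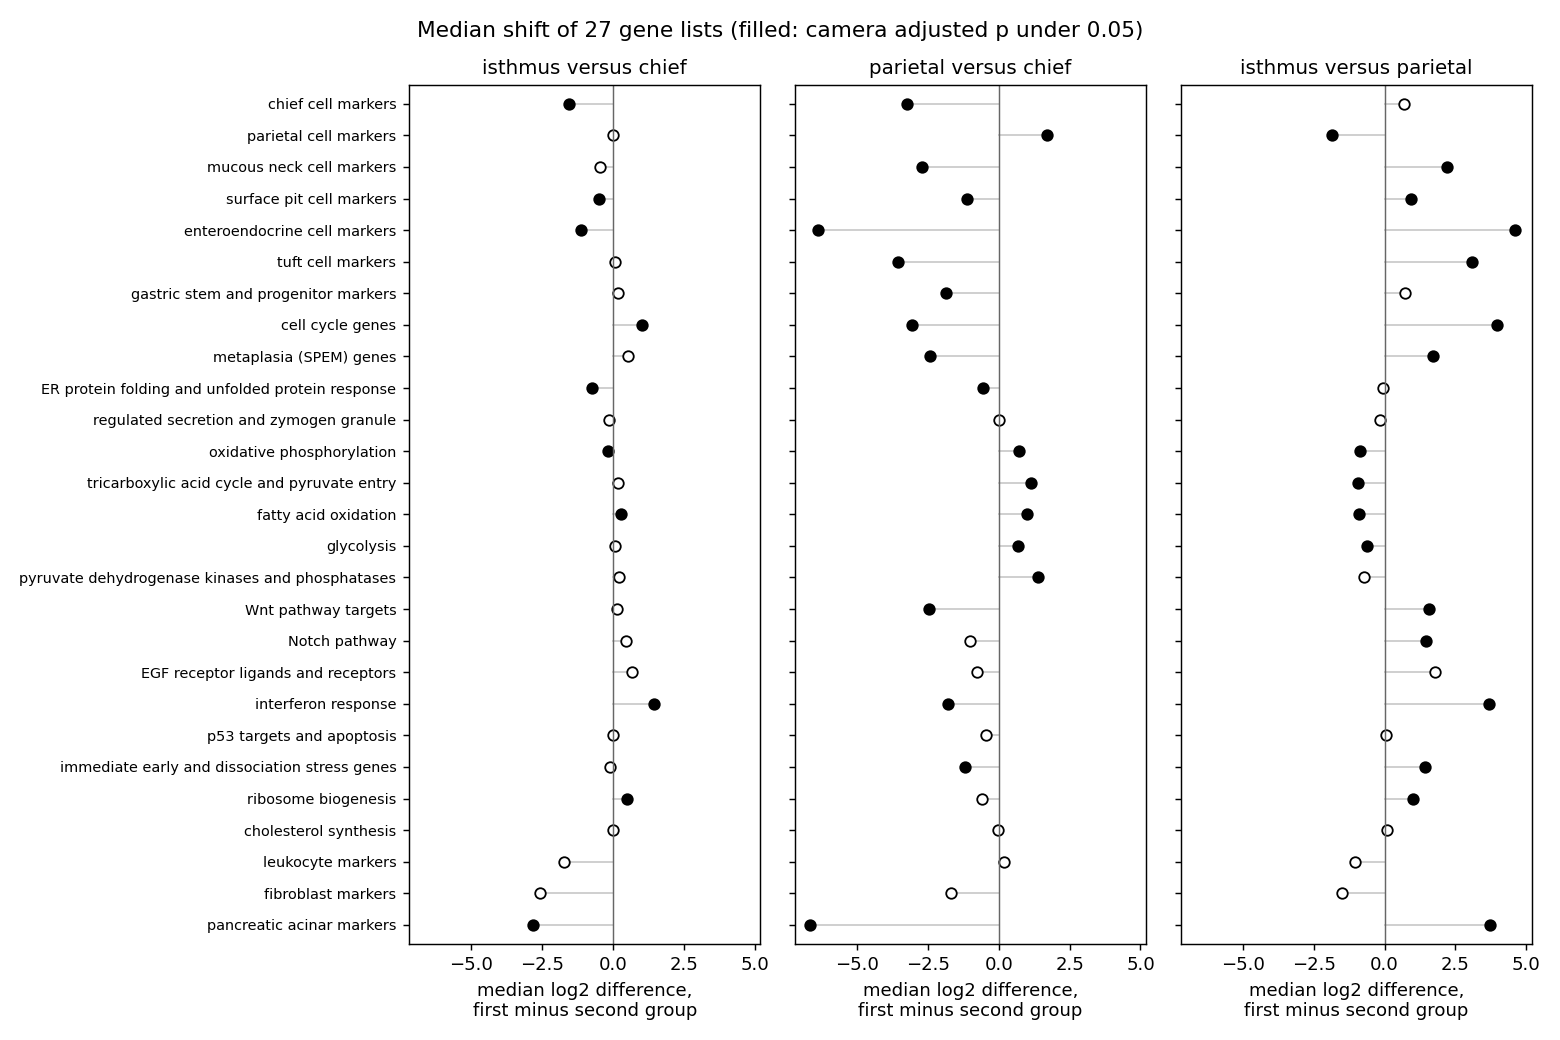
Median log2 difference over the tested members of each of 27 gene lists (horizontal axis, first minus second group; lists on the vertical axis) in the 3 comparisons, with filled points where camera's adjusted p was under 0.05. The enteroendocrine list had medians of -6.38 in parietal against chief and 4.60 in isthmus against parietal samples (-4.28 and 3.04 floored), the cell cycle list -3.07 and 3.96 (-2.20 and 3.27 floored), and the oxidative phosphorylation list 0.72 and -0.88, while its median of -0.19 in isthmus against chief turned to 0.03 after quantile normalization.

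The isthmus samples were last compared with the parietal samples. Cell cycle genes were higher in the isthmus samples, with Mki67 26.2-fold higher (12.84 ± 0.21 against 8.13 ± 0.14 log2, SD, n = 3 each; adjusted p = 5.03e-07), Tpx2 at least 20.1-fold and Top2a at least 30.7-fold. Interferon response genes were higher too, with Ifit1, an antiviral RNA-binding protein, at least 34.9-fold (adjusted p = 0.000127) and Oasl2 at least 47.2-fold. Parietal genes were lower, with Slc26a7 at least 52.4-fold lower (adjusted p = 5.96e-06), the potassium channel subunit Kcne1 at least 40.2-fold, Atp4a 2.91-fold and Atp4b 3.58-fold. Cblif was 5.25-fold higher in the isthmus samples (adjusted p = 0.00117), while Gper1, Bhlha15 and Lgr5 were not called (limma adjusted p = 0.689, 0.739 and 0.822). The means of Bhlha15 and Lgr5 lay below the array medians in both groups, and that of Gper1 lay near them in the isthmus group, so these values do not show that the groups are alike.

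Further large differences were those of Peg3, at least 32.4-fold higher, Tm4sf5, a membrane protein of the tetraspanin-like family, at least 44.6-fold, the transcription factor Maff at least 26.5-fold, and Gins1, a subunit of the replicative helicase complex, at least 17.1-fold. In the other direction B4galnt2 was at least 112-fold lower in the isthmus samples, Gpr155 at least 74.5-fold lower, Egf, the epidermal growth factor, at least 29.8-fold lower, and Vegfb, a vascular growth factor, lower by -3.71.

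Of 39 cell cycle genes 33 rose and 1 fell, 34 and 1 when adjusted over the list alone (median 3.96, 3.27 floored, camera adjusted p = 1.6e-17; adjusted p = 0.0748 with an estimated correlation). Of 21 interferon response genes 16 rose, 20 when adjusted over the list alone (median 3.68, 2.57 floored, camera adjusted p = 3.02e-08, held with an estimated correlation at 0.0485). Of 20 ribosome biogenesis genes 11 rose and 1 fell, also when adjusted over the list alone (median 1.02, camera adjusted p = 0.000177; adjusted p = 0.118 with an estimated correlation), with the nucleolar proteins Gnl3 and Nop58 up by 2.48 and 1.81. Of 22 immediate early and stress genes 12 rose and 1 fell, 14 and 1 when adjusted over the list alone (median 1.44, camera adjusted p = 0.000177, held at 0.0485), with Klf4 up by 4.05 and Atf3 by 3.41. Of 13 Wnt targets 6 rose, 7 when adjusted over the list alone (median 1.56, 1.22 floored, camera adjusted p = 0.0138; adjusted p = 0.0793 with an estimated correlation and 0.0902 with the stricter filter), among them Axin2 at least 5.88-fold and the cyclin Ccnd1 5.38-fold. Of 11 Notch pathway genes 4 rose and 1 fell, 6 and 1 when adjusted over the list alone (median 1.45, 1.10 floored, camera adjusted p = 0.0194; adjusted p = 0.118 with an estimated correlation and 0.0784 with no filter). Notch2 rose at least 33.3-fold by the probe set used, while its other probe set rose less, to 7.69 log2 in the isthmus from 5.88 in the parietal samples.

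Of 10 neck cell markers 9 rose, also when adjusted over the list alone (median 2.21, 2.11 floored, camera adjusted p = 1.55e-05; adjusted p = 0.0748 with an estimated correlation), and of 10 pit cell markers 6 rose and 1 fell, 7 and 1 when adjusted over the list alone (median 0.93, camera adjusted p = 0.0013; adjusted p = 0.112 with an estimated correlation). Of 14 enteroendocrine markers 10 rose, 12 when adjusted over the list alone (median 4.60, 3.04 floored, camera adjusted p = 3.58e-07, held at 0.0399), with Chga at least 62.3-fold and Ghrl, the hormone ghrelin, at least 81.2-fold higher. Of 6 tuft cell markers 2 rose, also when adjusted over the list alone (median 3.08, 1.14 floored, camera adjusted p = 0.0292; adjusted p = 0.218 with an estimated correlation). This call ended without isthmus replicate 2 or 3 (adjusted p = 0.0503 and 0.0507, range 0.00183 to 0.218). Of 15 metaplasia genes 9 rose, and 10 rose and 1 fell when adjusted over the list alone (median 1.70, 1.45 floored, camera adjusted p = 0.000418; adjusted p = 0.248 with an estimated correlation), and without parietal replicate 2 the median was 2.79 (adjusted p = 0.000183). Of 5 pancreatic acinar genes 2 rose, 3 when adjusted over the list alone (floored median 1.67, camera adjusted p = 0.0214; adjusted p = 0.118 with an estimated correlation and 0.0601 without isthmus replicate 2, range 0.00242 to 0.126).

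Of 21 parietal cell markers 18 fell, also when adjusted over the list alone, and 0 rose (median -1.84, camera adjusted p = 6.27e-12; adjusted p = 0.0793 with an estimated correlation). All 45 genes of oxidative phosphorylation fell (median -0.88, camera adjusted p = 1.95e-30; adjusted p = 0.0695 with an estimated correlation), as did 18 of 19 genes of the tricarboxylic acid cycle (median -0.94, camera adjusted p = 8.82e-12, held at 0.0271) and 13 of 19 of fatty acid oxidation (median -0.90, camera adjusted p = 5.59e-07, held at 0.0399), the same numbers when adjusted over the list alone. The pyruvate carrier Mpc1 fell by 1.74 and Echs1 by 1.81. Of 15 glycolysis genes 8 fell and 1 rose, 8 and 2 when adjusted over the list alone (median -0.62, camera adjusted p = 0.0011; adjusted p = 0.118 with an estimated correlation), with Ldhb lower by -2.08 and the lactate transporter Slc16a1 higher by 1.25. The other 10 lists gave no call. Of 10 chief cell markers 3 rose, Rab3d, Cblif and Pgc, by 2.41, 2.39 and 0.74, and Xbp1 fell by 0.87, also when adjusted over the list alone (median 0.68, camera adjusted p = 0.13). This list was called without parietal replicate 1 (adjusted p = 0.0252, range 0.025 to 0.351). The ER list had a median of -0.06, or -0.02 floored, a mean of 0.05 and a test pointing down (adjusted p = 0.92). The other camera adjusted p-values were 0.162 for stem and progenitor markers, 0.486 for regulated secretion, 0.139 for pyruvate dehydrogenase kinases, 0.333 for EGF receptor genes, 0.801 for p53 targets, 0.955 for cholesterol synthesis and 0.757 for the leukocyte and fibroblast lists.

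The genes Kit and Plvap were at 5.03 to 6.47 and 0.01 to 3.81 log2 on the isthmus arrays, below every parietal array. Of the lists with fewer than 5 tested members, all 3 intestinal genes tested were higher than in the parietal samples, by a floored median of 4.11, among them the lectin Lgals4 by 4.47. By limma 1696 genes were higher and 1339 lower in the isthmus than in the parietal samples, 2475 of them by at least 2-fold, and the groups did not overlap for 4899 genes, 44.3%, where chance gives 10%. The median log2 difference of all genes was 0.09. Centring each array moved it to -0.13 and the counts to 1359 higher and 1819 lower, so that 42.8% of calls were higher rather than 55.9%. Camera called 17 of 27 lists, 12 up and 5 down, 5 of them with an estimated correlation, and fry called 21.

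Genes higher in one group than in both others were counted last. The chief samples had 71, among them Sostdc1, Gper1, Fes, Derl3, Tmed6 and Syne4. The isthmus samples had 14, among them Parp14, Usp18, Slc25a25, Nr1h4, Cwc22 and Ehd4, and the parietal samples had 801, among them B4galnt2, Tmem178, Rnase1, Gpr155, Slc26a7 and Fabp1. These were picked among genes with a mean signal above the mean array median and no overlap with either other group. Genes outside that limit, such as Mug1 and Hbb-b2 in chief, Serpinb6b in isthmus and Speer4cos in parietal samples, ranked above some or all of those named. In 100 simulations of unchanged groups the highest count was 0. Hardly any gene passes when no group differs, so they cannot show what shared arrays add where many genes differ. Independent lists of the same sizes would share 18.6, 6.45 and 142 genes. The arrays of a group enter both of its comparisons and could not be split, so part of the excess may come from the shared arrays. Without chief replicate 1 the counts were 12 for chief and 0 for isthmus, without isthmus replicate 1 they were 21 and 0, and without isthmus replicate 2 they were 34 and 4. The chief count was 42 without chief replicate 3, and the isthmus count was 6 without isthmus replicate 3 and 9 without parietal replicate 3. Without parietal replicate 3 the parietal count was 527.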

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

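The annotation used here names no single gene for 10092 probe sets, and these entered no comparison of genes. Of the 4269 among them that passed the same filter, 63 were called between isthmus and chief samples (5 higher and 58 lower in isthmus), 1.48% of those tested. Between parietal and chief samples 450 were called, 141 higher and 309 lower in parietal, and between isthmus and parietal samples 423, 237 higher and 186 lower in isthmus. These are 10.5% and 9.91% of those tested. No control samples were used for them here, and they were singled out because signals past the threshold lay outside the genes compared. What transcripts they measure was not analysed here.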

How the results depend on the processing

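The pseudocount of 16 and leaving out both arrays with high Xist were chosen after the values had been seen. No result passed in opposite directions under any 2 settings, although a list that passed in neither could change sign unseen by that count. Of 34 named genes called between isthmus and chief samples, 3 were called under every alternative and 31 were lost under at least 1. For parietal against chief samples 85 of 120, and for isthmus against parietal 90 of 116, were called under every alternative. Of the lists called in these 3 comparisons, 0 of 10, 6 of 19 and 5 of 17 were. The estimated correlation ended all 10 in the first. The cause of these changes was not tested, except that a pseudocount by its construction draws low signals together.

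The 42 genes higher in isthmus than in chief samples became 87 with a pseudocount of 64, 13 with no filter, 8 without a trend, 17 with array weights, 19 with only the 2 groups compared, 26 with the mean of all probe sets of a gene and 19 without both arrays with high Xist. The 137 lower became 231 with a pseudocount of 64, 211 with a pseudocount of 16, 82 with no filter, 84 after quantile normalization, 34 without a trend, 77 with array weights, 72 with only the 2 groups compared, 83 at a fold of at least 2 and 55 without both arrays with high Xist. Of lists in this comparison, 10 became 0 with an estimated correlation and 6 by fry. Without both arrays with high Xist the 1175 genes higher and 1500 lower in parietal than chief samples became 645 and 961. With an estimated correlation the 19 lists of parietal against chief became 6 and the 17 of isthmus against parietal became 5.

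The 71 genes higher in chief than in both other groups became 134 and 116 with a pseudocount of 64 and 16, 47 with no filter, 46 after quantile normalization, 24 without a trend, 44 with array weights and 32 without both arrays with high Xist. The 14 of isthmus became 50 and 30 with a pseudocount of 64 and 16, 7 with no filter, 24 with the stricter filter and 5 without a trend. The 801 of parietal became 467 without both arrays with high Xist.

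The groups share replicate numbers. With the replicate number as a block, a replicate block, the 42 genes became 21 and the 14 became 8, and the 137 became 118. After removing group means, isthmus and chief profiles of the same number correlated at 0.032, 0.033 and 0.078. Those of different numbers correlated lower, at -0.044 to 0.010. With the parietal samples, profiles of the same number correlated at -0.031 to 0.003. The numbers were not read as pairs in the main fit, but these small values leave open whether isthmus and chief samples of equal number share a collection.

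Leaving out 1 array at a time gave 0 to 45 genes higher and 19 to 138 lower in isthmus than in chief samples, with 8 to 11 lists. Both lowest gene counts came without chief replicate 1. It gave 757 to 1171 genes higher and 1137 to 1462 lower in parietal than chief samples, with 17 to 21 lists, and 1302 to 1781 higher and 928 to 1441 lower in isthmus than parietal samples, with 15 to 18 lists. The counts of genes highest in 1 group ran from 12 to 72 for chief, 0 to 15 for isthmus, where 0 came without chief replicate 1 or isthmus replicate 1, and 527 to 802 for parietal.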

Other observations

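The tests of the cell cycle and interferon lists below and the choice of genes given per array came after the results had been seen. The lists matched on signal were set out before their outcome was known but after quantile normalization had been run, and the regroupings of arrays were planned. Cells collected as different types shared abundant transcripts of the gastric mucosa. Gkn1, a secreted protein of surface cells, was at 13.83 to 15.21 log2 on all 9 arrays, and the proton pump subunit Atp4b was at 11.97 to 12.80 on the arrays of Mist1+ cells. Gast, a hormone of antral cells, was above 11 log2 in chief replicates 1 and 3 and isthmus replicates 1 and 3 and was 3.65 and 3.66 in replicate 2 of each. The Y-linked gene Eif2s3y was 2.84 in parietal replicate 1, 10.63 in chief replicate 3 and 11.11 to 11.59 on the other 7 arrays, while Xist was 13.13 in the first, 11.72 in the second and 4.46 to 5.93 elsewhere. The sex of the animals is not given in the sources used here.

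The cell cycle list was higher in isthmus than in chief samples by a mean log2 value of 0.98 (SE 0.447). A lower share of chief cell RNA would raise other cell types alike, yet 40 members of other lineage lists in the same signal range shifted by -0.52 (SE 0.176), a difference of 1.49 (SE 0.532) from the cell cycle list, or 1.35 (SE 0.476) with each array at the higher of its own value and its array median. The other lineage members include enteroendocrine markers, a list that was itself lower, and a fall of their own would widen this difference. It was not recomputed without chief replicate 1. The call of the cell cycle list was kept without that array, with a smaller median (camera adjusted p = 0.00134, median 0.60 against 1.04). It was also kept under another scaling (1.85e-06 after quantile normalization, median 1.03), within a range of 1.97e-11 to 0.297 over all alternatives, the highest with an estimated correlation. More dividing cells among the Mist1+ cells left after ablation may account for it, which was not tested here. No member passed by itself, with 7 of 39 at an unadjusted p under 0.05 by limma, and a difference in the animals or in cell recovery stays open and untested.

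The interferon list was higher in isthmus samples by a mean of 1.70 (SE 0.319), while its 1 called member, Usp18, lost its call whichever array was left out. The leukocyte list, 5 tested genes fixed before the data were examined and held by no other list, shifted by -1.91 (SE 0.866). With the same floor the interferon shift was 1.29 (SE 0.273) and the leukocyte shift -0.99 (SE 0.234). Its bright member Cd74 was 9.21 log2 in chief and 6.66 in isthmus samples. These 5 genes thus showed no rise of leukocyte RNA in the isthmus samples. Each of the 5 had an array below its array median, so they do not exclude added leukocyte RNA. Quantile normalization left the call in place (adjusted p = 9.22e-07, median 1.71; range 1.23e-09 to 0.151, the highest with an estimated correlation). A response of the tissue to the loss of Lgr5+ cells or to the ablation agent may account for it, and the groups do not part these.

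The brightest genes fell together in isthmus samples. Of the 50 brightest, 50 were lower, with a median of -0.42, and 0.06 after quantile normalization. Against 10000 random lists matched on signal, oxidative phosphorylation lay at percentile 74.56 (83.53 in a second matching; random medians -0.32 to -0.13), so a shift shared by equally bright genes may account for its fall. The pit list lay at percentile 0.14 (0.26 in the second; random medians -0.41 to 0.04), below what such a shift gives, although quantile normalization ended its call (median -0.51 before and -0.08 after, adjusted p = 0.171). The chief and ER folding lists lay at percentile 0 and 0, under all 10000 lists. Both were also lower in parietal than in chief samples (medians -3.24 and -0.57), so the same limit of the matching holds for them. Oxidative phosphorylation was higher there (median 0.72), so its percentile may be too high.

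For each pair of groups, 10 splits of the 6 arrays are too few for a share under 0.05. For genes, 1 of 10 splits reached the real count in each pair. The real split of isthmus and chief arrays gave 179 genes and the highest other split 0, parietal and chief 2675 and 0, and isthmus and parietal 3035 and 0. Every other split mixes arrays of both groups, which puts a real difference into the spread of the fit. The low counts of genes there therefore do not speak for the real grouping. For lists, the real split gave 10 and the highest other 8 in the first (1 of 10 splits as large), 19 and 16 in the second (1 of 10), and 17 and 17 in the third (2 of 10). The mixed splits keep a part of any real difference, so their list calls are not a rate of false calls. For genes highest in 1 group, 1 of 100 splits of the 9 arrays reached the 801 of parietal, the real one, and the highest other gave 704. That other split kept the 3 parietal arrays together and regrouped only chief and isthmus arrays. The parietal arrays stand apart from both other groups, so this rank follows from a structure of the samples. It excludes neither a batch nor samples that are not separate animals. For chief 3 of 100 reached 71 and the highest other gave 801, and for isthmus 3 of 100 reached 14 and the highest other gave 688. The other splits that reached them gave these names to the 3 parietal arrays, a structure of the samples. They say nothing of chance between chief and isthmus arrays, for which the 10 splits are too few.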
